A study of Drosophila melanogaster with 14 samples.

How the data were processed

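Polyadenylated RNA from testes was sequenced as TruSeq libraries on a MiSeq, per the labels, which describe the 2 libraries of each genotype as biological replicates. Reads were processed with TopHat, Cufflinks and Cuffdiff and the genome builds dm3 and dm6 are named, per the submitters' processing notes. Their versions and the use of strand are not given in the sources used here. The authors deposited a table of FPKM per gene (fragments scaled by transcript length and by the fragments of the library) for each library, and tables of 6 comparisons with p-values and q-values per transcript. No count table was used, so no count model was fitted. FPKM divides by the fragments of the whole library, so a few abundant genes can lower the values of all others. Because FPKM is also scaled by length, a share of summed FPKM, such as that of CG18628, is not a share of fragments. An exact 0 can be a failed estimate. Genes at 0 are therefore said to be listed at 0.

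Groups were taken from the labels of the 14 libraries. The per-library tables used 2 annotations: 10 libraries had gene symbols as identifiers (16745 genes), and the 4 libraries of CG9879 and mip40/bam had FBgn identifiers (17480 genes). They were joined by symbol. Of 16166 symbols used once in both, 16084 lay on the same chromosome at overlapping positions, of which 15718 (97.7%) had the same start and end, and 6 with a failed estimate in at least 1 library were removed, which left 16078 genes. The annotation difference coincides with genotype in CG9879 against wt and mip40/bam against bam. Of the joined genes 15814 (98.4%) had their FBgn number in the BDGP6.54 annotation, which gave biotypes and overlaps; coordinates printed are those of the files. Exons of 5059 genes overlap those of another gene on either strand. Reads of overlapping or antisense genes, and of near-identical copies such as Amy-d and Amy-p, scpr-A and scpr-C, the Mst84D genes and the protamine genes Mst35Ba and Mst35Bb, cannot be told apart with certainty, so their values are uncertain. Among the genes named, bam, Mst87F, twe, tbrd-1, Rpt3R, Prosalpha2, RpL39, RpS29, Act57B and Syx1A share exons with another gene, and vas was among the genes without a match, so its overlaps were not looked up.

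Genes with an FPKM of at least 1 in at least 2 libraries were kept (12971). limma (version 3.58.1, in R 4.3.3) was fitted to log2(FPKM + 1) with an intensity trend over all 14 libraries and 7 groups, which left 7 residual degrees of freedom plus a prior of 1.82. Contrasts were tested in a two-sided way, with Benjamini-Hochberg adjustment over the genes of each contrast, and a gene was called at an adjusted p under 0.05. There were 6 main comparisons, those with a deposited table, 3 secondary ones and the interaction. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for joining, tables and plots. The numbers of fragments were worked out from the confidence intervals of the FPKM values: 4910000 and 4460000 in bam, 3790000 and 4650000 in comr, 4570000 and 4420000 in can, 3120000 and 3500000 in CG9879, 3450000 and 3620000 in mip40, 7690000 and 7140000 in mip40/bam and 3210000 and 3370000 in wt. The summed FPKM ranged from 661746 to 1297043. On simulated data with known changes, 72% of genes changed 2-fold and 96% of those changed 4-fold were called for bam against wt (11358 genes), 85% and 96% for comr (11371), 80% and 94% for can (11373), 80% and 97% for CG9879 (11383), 85% and 98% for mip40 (11363) and 85% and 95% for mip40/bam against bam (9085). The share of calls that were false was 3% to 6.9%. Each simulation changed 200 genes, all well above 0, plus a small set with a weaker shift that counted as true. The other genes were left unchanged. The comparisons below have far more calls, also among genes near 0, so these shares do not carry over to them.

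The 19 gene lists were spermatid differentiation, cup genes, meiotic cell cycle, tMAC and tTAF subunits, germline stem cells and spermatogonia, DNA replication, Y-linked genes, testis-specific proteasome subunits, general proteasome subunits, cytoplasmic ribosomal proteins, somatic hub and cyst cells, accessory gland and ejaculatory duct, muscle, fat body and haemolymph, neurons, photoreceptors, eggshell and oogenesis, heat shock, and antimicrobial peptides and immune response. Symbols were matched exactly. The tMAC and tTAF list holds mutated genes of the series and also testis chromatin regulators such as tbrd-1. Lists were tested with camera at a preset correlation of 0.01, adjusted over 190 tests of 19 lists in 10 comparisons, and again with an estimated correlation, with which no list call held (lowest adjusted p = 0.246, camera). The 2 lists of genes chosen in comr against wt were tested in mip40/bam against bam in the same way, adjusted over these 2 tests, an adjustment added after the unadjusted values were seen. List medians include genes listed at 0 in a group, whose fitted change is no bound.

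The groups, comparisons, lists, tests, named-gene rule and most alternatives were fixed before the data were examined. The rule names the 5 mutated genes, 11 marker genes (dj, Mst87F, fzo, Mst35Ba, twe, CycB, bol, vas, aly, sa and betaTub85D), up to 4 called members per list that passed, by mean FPKM, and the 6 largest rises and 6 largest falls per comparison (4 for the interaction) among called genes with a name, a mean FPKM of at least 10 in the higher group and no overlap of the groups' libraries. Of its 12 largest changes per comparison, 8 to 12 were not protein-coding or shared exons (6 of 8 for the interaction). The largest changes named are therefore those among protein-coding genes that share no exon, a choice made after seeing the data, and some of either set are left out of the text. Alternatives tried were pseudocounts of 0.1 and 5, no filter and a filter at an FPKM of 5, median-of-ratios scaling, quantile normalization, equal summed FPKM, no intensity trend, a replicate block, fits of the groups compared alone, an estimated correlation, a 2-fold threshold, the authors' tables and leaving out each library. Added after seeing the data were leaving out the 4 libraries with accessory gland transcripts, and restricting the genes to protein-coding genes that share no exon or to genes with the same start and end in both annotations, and for the comr lists and the lists of the interaction to genes with a mean FPKM of at least 1 in bam or mip40/bam. Overlaps of calls were set beside 20 simulated datasets of unchanged groups that share 2 controls. Non-protein-coding genes are described only in the closing part.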

Results

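RNA from adult testes of the fruit fly Drosophila melanogaster was sequenced in 7 genotypes with 2 biological replicates each, 14 libraries in all. Per the labels, each library came from 50 testes of 3-day-old males. The genotypes were wild type (wt), mutants of bam, comr, can, CG9879 and mip40, and the double mutant mip40/bam. bam is a switch gene that ends the divisions of spermatogonia, the early germ cells, so bam mutant testes accumulate such cells and lack spermatocytes, the cells that enter meiosis. comr and mip40 encode subunits of tMAC, a testis form of a chromatin complex, and can encodes a testis form of a TBP-associated factor (tTAF). Mutants of comr and can arrest as spermatocytes before the meiotic divisions. The values were FPKM per gene, and 12971 genes passed the filter on low values and were tested. The depth that the tables imply was 3120000 to 7690000 fragments per library, highest in mip40/bam (7690000 and 7140000), against 3210000 and 3370000 in wt. Between 8167 and 11271 genes per library reached an FPKM of at least 1. The gene CG18628 had the highest FPKM in each library, with 2.7% to 22.5% of the summed FPKM (22.5% and 21.2% in mip40/bam, 11.1% and 16.1% in bam). Across genes, which are not independent replicates, replicates correlated at r = 0.94 to 0.985 on the log2(FPKM + 1) scale.

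The first principal component held 64.4% of the variance and the second 16.2%. On the first, the libraries of comr (-59.42 and -57.76), mip40 (16.35 and 29.42) and can (73.51 and 75.18) lay apart. Those of CG9879 and wt lay together at 166.71 to 171.74, and those of bam and mip40/bam lay close, at -191.36 to -184.95. On the second component CG9879 (-61.23 and -65.04) and wt (-59.66 and -59.03) lay close without overlap. Group means across genes correlated most closely for CG9879 and wt (r = 0.963) and for bam and mip40/bam (r = 0.941). Next were can with mip40 (r = 0.864), comr with mip40 (0.857), can with wt (0.792) and with CG9879 (0.791) and comr with can (0.77), while the correlation of bam with wt was 0.246. All means below are of 2 libraries, log2 fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes, and adjusted p-values are limma's with Benjamini-Hochberg adjustment. The p-values rest on the spread between replicates pooled over all 7 groups, also those outside a comparison. The median absolute log2 difference between replicates ran from 0.07 in mip40/bam to 0.16 in can.

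The 5 mutated genes were examined in every group. CG9879 (FBgn0031444, chromosome 2L, 2665062 to 2666265) was at 1.03 ± 0.38 FPKM (SD, n = 2) in the CG9879 mutant and 58.7 ± 7.49 in wt, a log2 fold change of -4.89 (SE 0.17, limma adjusted p = 1.8e-07). Its mean was 24.0 FPKM in can, 12.2 in mip40 and 0.35 in comr, and it was listed at 0 in all 4 libraries of bam and mip40/bam. comr (FBgn0034667, chromosome 2R, 21864870 to 21866859) was at 18.5 ± 0.94 FPKM in the comr mutant against 7.47 ± 1.44 in wt, a log2 difference of 1.21 that was 0.08 with median-of-ratios scaling (adjusted p = 0.658, limma), and was listed at 0 in the bam and mip40/bam libraries. can (FBgn0011569, chromosome 3L, 10263909 to 10267111) was at 51.4 ± 1.75 FPKM in the can mutant against 15.5 ± 0.22 in wt, a log2 difference of 1.66 that was 0.53 with median-of-ratios scaling. mip40 (FBgn0034430, chromosome 2R, 19291105 to 19292196) was at 20.5 ± 0.47 FPKM in the mip40 mutant and 21.8 ± 1.34 in wt, a log2 difference of -0.09 (adjusted p = 0.315, limma). This difference depended on the scaling, at -1.15 with median-of-ratios scaling (limma adjusted p = 8.79e-07), -0.64 with quantile normalization (1.66e-05) and 0.21 at equal summed FPKM (0.0487). In mip40/bam it was at 26.6 FPKM against 59.8 in bam, lower by a log2 fold change of -1.14 (limma adjusted p = 6.3e-06). Its mean was 102.3 FPKM in comr, 130.5 in can and 41.2 in CG9879. bam (FBgn0000158, chromosome 3R, 25243039 to 25245057), which shares exons with CG11854, was at 2.91 FPKM in bam replicate 1 and listed at 0 in replicate 2, 0.79 in mip40/bam, 2.97 in wt, 27.2 in comr, 17.2 in can and 30.7 in mip40. The alleles are not given in the sources used here, so RNA of the mutated gene in the comr and can libraries does not check those labels, while the level of CG9879 went with its label. The level of mip40 was lower in its mutant than in comr and can, but against wt the difference depended on the scaling, so it checks that label only in part.

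**Figure D1:**
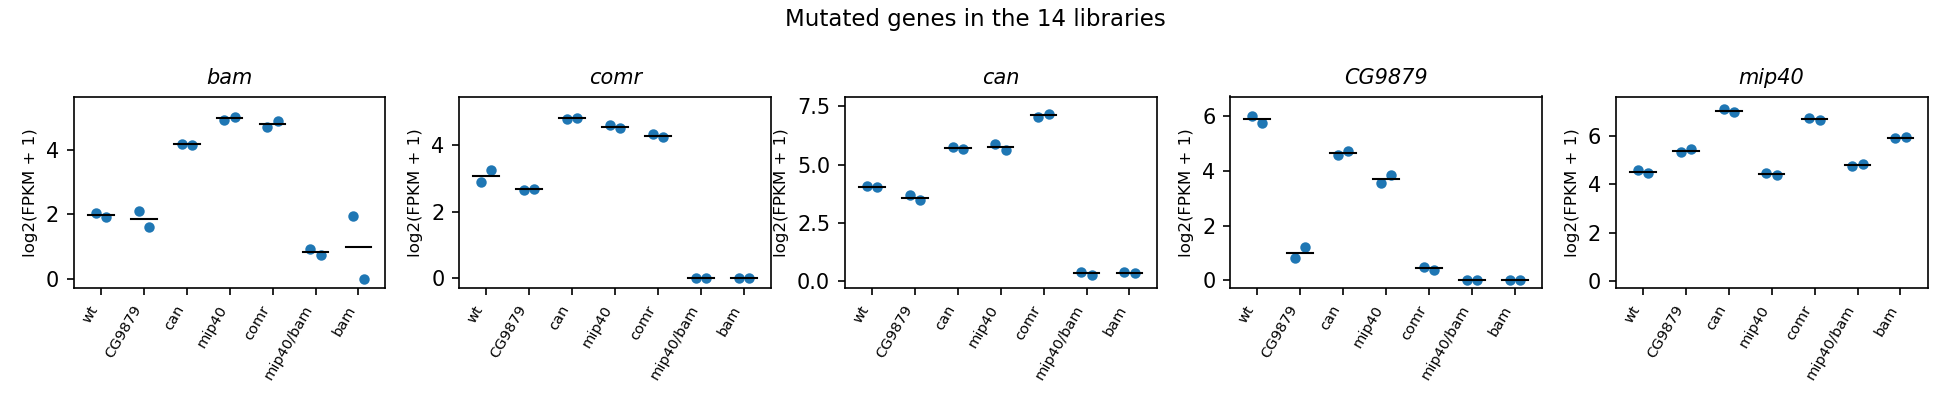
Each panel gives one mutated gene, with log2(FPKM + 1) on the vertical axis and the 7 genotypes on the horizontal axis; points are libraries and lines are means of 2. CG9879 is near 1 FPKM in its own mutant, while comr, can and mip40 remain detected in theirs.

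Accessory gland transcripts were present in 4 of the 14 libraries. The accessory gland is a male organ next to the testis that makes seminal fluid proteins. Its list, with ejaculatory duct genes, took 6.13% of the summed FPKM in comr replicate 2 against 0.0376% in replicate 1, 1.84% in CG9879 replicate 2 against 0.0271%, 1.26% in can replicate 1 against 0.0185% and 0.998% in wt replicate 1 against 0.0126%. The 6 libraries of bam, mip40 and mip40/bam had 0.0358% to 0.122%. The comparisons below that use comr, CG9879, can or wt therefore each contain at least 1 library with such transcripts.

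**Figure D2:**
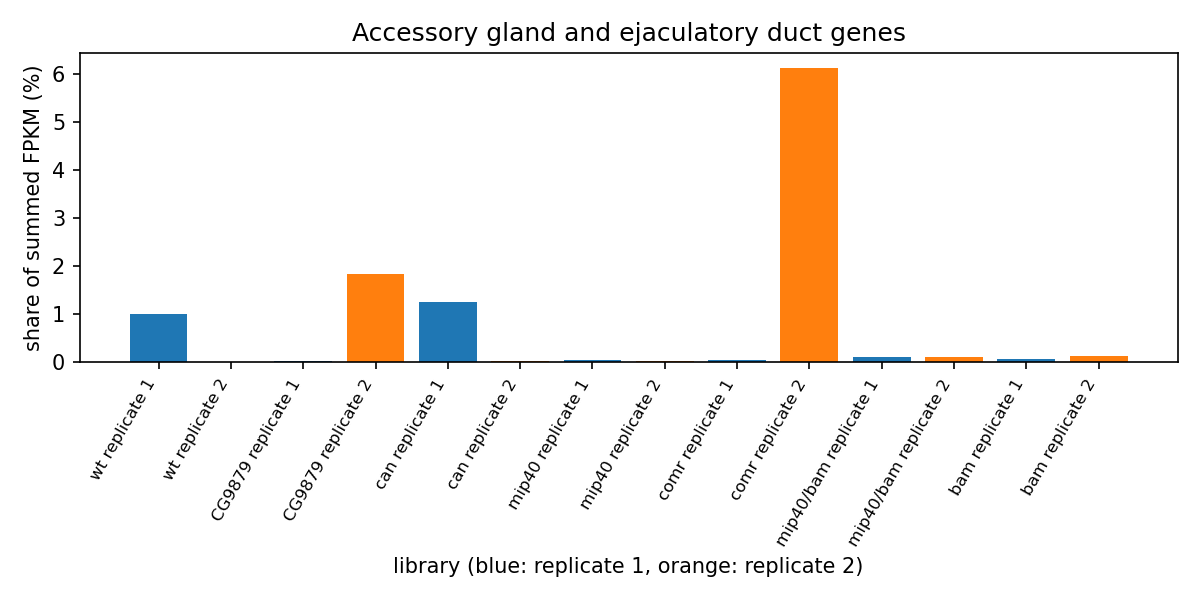
Bars give the percentage of each library's summed FPKM in accessory gland and ejaculatory duct genes, for the 14 libraries in pairs of replicates. One library of each of wt, CG9879, can and comr reaches 0.998% to 6.13%.

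The comparison of bam with wt addressed which genes depend on germ cells beyond the spermatogonial stage. Genes of late stages fell to near 0. dj, a sperm tail gene, was at 0.37 FPKM in bam and 1799 ± 86.7 in wt (SD, n = 2), a log2 fold change of -10.41 (SE 0.22, limma adjusted p = 1.04e-10), and betaTub85D, the testis beta-tubulin, changed by -10.22 (SE 0.16). Of the 32 measured genes of spermatid differentiation, 31 fell and 1 rose, with a median of -10.14 (camera adjusted p = 8.19e-12, adjusted p = 0.31 with an estimated correlation). Mst84Dc, loopin-1, S-Lap1 and ocn, which encode sperm proteins, changed by -11.70, -11.28, -11.26 and -11.12, and fzo, a mitochondrial fusion gene of spermatids, by -6.93. Mst35Ba, a protamine gene, was listed at 0 in both bam libraries and had 391.6 FPKM in wt. All 17 cup genes, with transcription reported after meiosis, fell (median -7.37, camera adjusted p = 6.17e-08, adjusted p = 0.27 with an estimated correlation), among them w-cup at -10.29 and soti at -8.99.

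Early germline genes rose in bam. vas, a germline RNA helicase, was at 533.9 ± 5.52 FPKM in bam and 15.75 ± 0.98 in wt (SD, n = 2), a log2 fold change of 5 (SE 0.07), and zpg, a germline gap junction gene, rose by 5.38 (SE 0.13). Of the 12 genes of germline stem cells and spermatogonia, 10 rose and 1 fell (median 3.57, camera adjusted p = 0.0224, adjusted p = 0.395 with an estimated correlation). Of 28 DNA replication genes, 27 rose and none fell, with a median of 3.93 (camera adjusted p = 1.57e-06, adjusted p = 0.246 with an estimated correlation). PCNA, the polymerase clamp, rose by 4.23 and geminin by 2.08. Cytoplasmic ribosomal protein genes rose in 90 and fell in 3 of 93 (median 3.62, camera adjusted p = 2.53e-17, adjusted p = 0.273 with an estimated correlation). General proteasome subunit genes rose in 26 and fell in 1 of 30 (median 0.88, camera adjusted p = 2.15e-04, adjusted p = 0.483 with an estimated correlation), but their median was -0.24 with median-of-ratios scaling, which ended the call (camera adjusted p = 0.849). The testis-specific proteasome genes, which are paralogs of general subunits, rose in 1 and fell in 13 of 14 (median -6.25, camera adjusted p = 4.48e-05, adjusted p = 0.246 with an estimated correlation), with Rpn12R at -7.51. Of 7 Y-linked genes, 6 fell and none rose (median -3.56, camera adjusted p = 0.00723, adjusted p = 0.246 with an estimated correlation), with ARY at -5.53. Among the 14 tMAC and tTAF genes, 3 rose and 10 fell (median -2.04, camera adjusted p = 0.0224, adjusted p = 0.433 with an estimated correlation), with Taf12L at -1.47 and aly at 0.53. Of the meiotic genes, bol, an RNA-binding translation regulator, changed by -4.67 and twe, the meiotic Cdc25 phosphatase, by -1.22, while CycB, the mitotic and meiotic cyclin B, was at 68.8 ± 4.88 FPKM in bam and 73.67 ± 7.72 in wt (adjusted p = 0.303, limma). Df31 rose by 5.96, rhi, a piRNA cluster protein gene, by 5.53 and Pxt by 5.51, and MtnD, a metallothionein gene, was listed at 0 in wt and had 264.1 FPKM in bam. The call of aly ended without bam replicate 2 (limma adjusted p = 0.0514) or wt replicate 2 (0.108), and aly was at -0.54 with median-of-ratios scaling. With protein-coding genes that share no exon, the germline list lost its call (camera adjusted p = 0.0988). For these lists the counts adjusted over the list alone were the same. In total 10201 genes were called, 5733 higher and 4468 lower (56.2% higher, but 38.3% with median-of-ratios scaling), and 4563 rose and 3786 fell at least 2-fold.

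**Figure D3:**
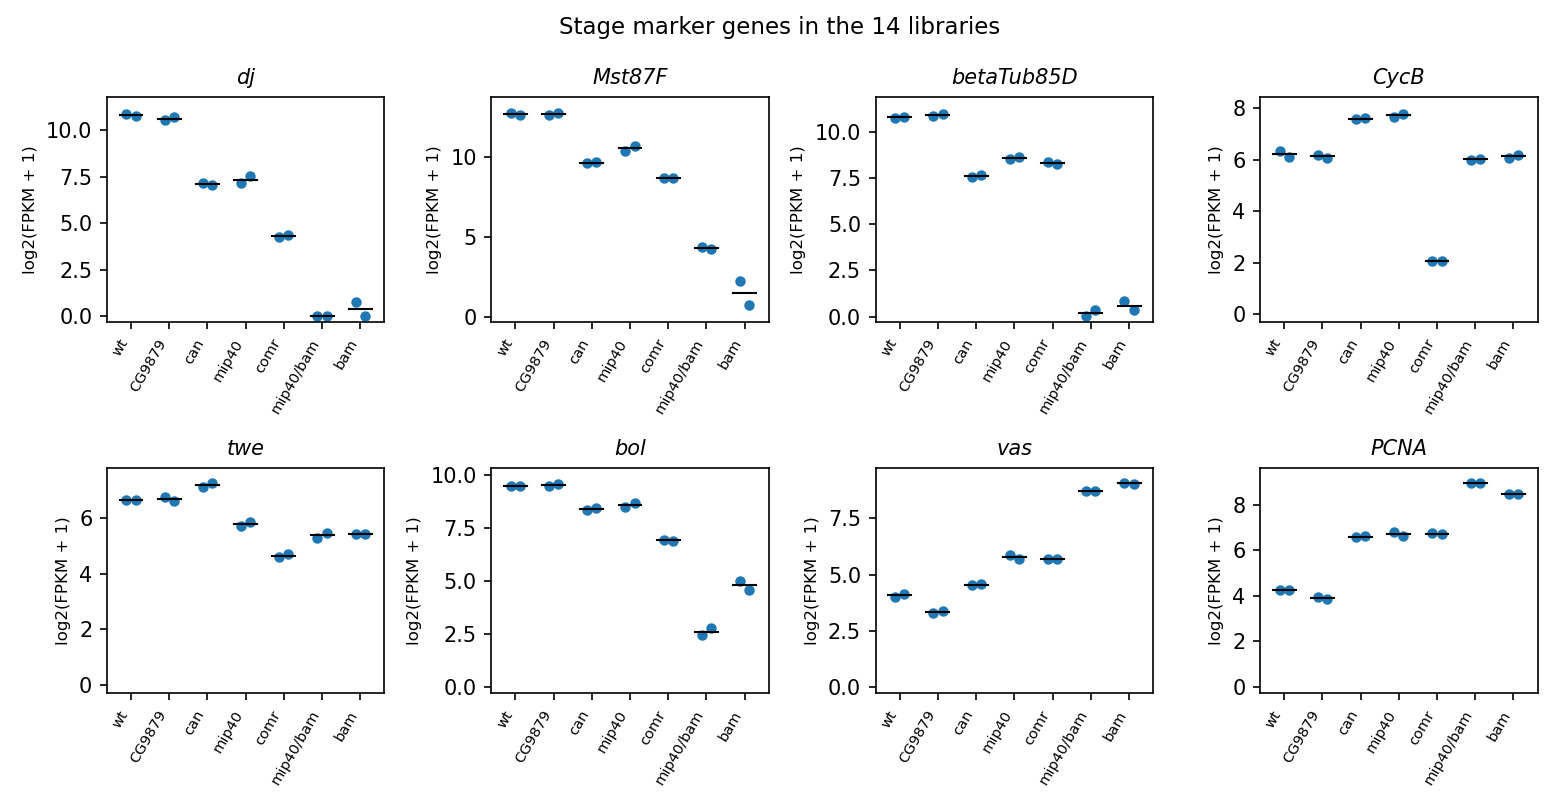
Each panel gives one gene, with log2(FPKM + 1) on the vertical axis and the 7 genotypes on the horizontal axis; points are libraries and lines are means of 2. dj and betaTub85D are near 0 in bam and mip40/bam and intermediate in can, mip40 and comr, and CycB is lowest in comr.

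The comparison of comr with wt addressed which genes change with the loss of this tMAC subunit. Whole testes were sequenced, so an effect on a gene and a change in the mix of cells cannot be told apart. This also holds for can and mip40 against wt. CycB was at 3.15 ± 0.01 FPKM in comr and 73.67 ± 7.72 in wt (SD, n = 2), a log2 fold change of -4.17 (SE 0.08, limma adjusted p = 1.48e-10). twe changed by -2.01 (SE 0.09), fzo by -5.58 and dj by -6.49. Of the 32 spermatid differentiation genes, 31 fell and 1 rose (median -3.13, camera adjusted p = 2.48e-10, adjusted p = 0.362 with an estimated correlation), with Mst84Dc at -1.57 and Mst35Ba at -4.64. Of 17 cup genes, 16 fell and none rose (median -4.94, camera adjusted p = 9.22e-08, adjusted p = 0.27 with an estimated correlation), from soti at -0.64 to w-cup at -8.71. The tMAC and tTAF genes, which include comr, can and mip40 themselves, rose in 14 of 14 (median 2.24, but 1.02 with median-of-ratios scaling, camera adjusted p = 4.13e-04, adjusted p = 0.277 with an estimated correlation), with aly at 2.55, sa at 2.21 and Taf12L at 2.05. DNA replication genes rose in 24 of 28 and fell in none (median 2.09, but 1.04 with median-of-ratios scaling, camera adjusted p = 8.43e-04, adjusted p = 0.27 with an estimated correlation), with PCNA at 2.47. Y-linked genes fell in 6 of 7 (median -2.49, camera adjusted p = 0.00479, adjusted p = 0.246 with an estimated correlation), with Pp1-Y2 at -4.83. Testis-specific proteasome genes rose in 4 and fell in 10 of 14 (median -3.42, camera adjusted p = 0.0102, adjusted p = 0.246 with an estimated correlation), with Rpt6R at 1.58 and Rpn12R at 0.55. Ribosomal protein genes rose in 89 and fell in 3 of 93 (median 1.64, but 0.40 with median-of-ratios scaling, camera adjusted p = 3.44e-10, adjusted p = 0.395 with an estimated correlation). General proteasome genes rose in 30 of 30 (median 1.25, but 0.02 with median-of-ratios scaling, camera adjusted p = 9.67e-06, adjusted p = 0.415 with an estimated correlation), a call that this scaling ended (camera adjusted p = 0.231).

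Single genes with large changes in comr were of mixed kinds. trpl, a cation channel gene best known from photoreceptors, was at 46.3 ± 2.17 FPKM in comr and 0.78 ± 0.17 in wt (SD, n = 2), a rise of 4.74, and LamC, the lamin C gene, rose by 3.81. Nos, the nitric oxide synthase gene, rose by 4.31, eIF4E-6 by 4.15 and Cpsf160, an RNA cleavage factor gene, by 3.93. scpr-A changed by -9.31, SIP2 by -8.78 and sut4, a sugar transporter gene, by -8.47, and Atg8b was listed at 0 in both comr libraries. The calls of Mst84Dc and soti ended with a pseudocount of 0.1 (limma adjusted p = 0.188 and 0.262), with quantile normalization and without the 4 libraries with accessory gland transcripts. That of Rpn12R ended without comr replicate 1 (limma adjusted p = 0.0507), and Rpn12R was at -0.68 with median-of-ratios scaling. For the lists named here the counts adjusted over the list alone were the same. In total 9913 genes were called in comr, 6295 higher and 3618 lower (63.5% higher, but 38.6% with median-of-ratios scaling), and 4849 rose and 3009 fell at least 2-fold.

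The comparison of can with wt addressed the same question for a tTAF subunit. CycB was higher, at 191.9 ± 3.07 FPKM in can against 73.67 ± 7.72 in wt (SD, n = 2), a log2 fold change of 1.37 (SE 0.08, limma adjusted p = 3.76e-07), and twe rose by 0.56, but was lower by -0.62 with median-of-ratios scaling. That scaling moved genes with a mean FPKM of at least 10 in both groups by a median of -1.16. The size of the CycB rise therefore depends on the scaling. dj changed by -3.72 (SE 0.22), betaTub85D by -3.18 and fzo by -0.94. Spermatid differentiation genes fell in 31 and rose in 1 of 32 (median -2.84, camera adjusted p = 7.91e-16, adjusted p = 0.27 with an estimated correlation). Cup genes fell in 16 of 17 and none rose (median -1.33, camera adjusted p = 1.07e-08, adjusted p = 0.27 with an estimated correlation), with w-cup at -4.76. tMAC and tTAF genes rose in 12 and fell in 1 of 14 (median 1.54, but 0.40 with median-of-ratios scaling, camera adjusted p = 0.0187, adjusted p = 0.415 with an estimated correlation), and Taf12L, a testis TAF12 paralog, rose by 3.56. DNA replication genes rose in 23 of 28 (median 1.48, but 0.63 with median-of-ratios scaling, camera adjusted p = 0.0224, adjusted p = 0.362 with an estimated correlation), with PCNA at 2.33, and with quantile normalization this call ended (camera adjusted p = 0.0573). Y-linked genes fell in 5 of 7 (median -0.50, camera adjusted p = 0.00877, adjusted p = 0.246 with an estimated correlation), with ARY at -1.79. General proteasome genes rose in 29 of 30, or 30 adjusted over the list alone (median 1.40, but 0.22 with median-of-ratios scaling, camera adjusted p = 7.29e-06, adjusted p = 0.415 with an estimated correlation). Ribosomal protein genes rose in 89 and fell in 2 of 93, or 90 and 3 adjusted over the list alone (median 1.56, but 0.39 with median-of-ratios scaling, camera adjusted p = 9.11e-11, adjusted p = 0.372 with an estimated correlation). The other counts were the same when adjusted over the list alone. Of the 14 testis-specific proteasome genes, 3 rose and 7 fell, and the list test did not pass (median -0.30, camera adjusted p = 0.0768). Mks1, a cilium transition zone gene, was at 64.36 ± 9.97 FPKM in can and 2.97 ± 1.45 in wt, a rise of 4.08, and CCHa1, a neuropeptide gene, rose by 4.26. scpr-A changed by -9.21, Acyp, an acylphosphatase gene, by -5.41, lobo by -5.38, Mst35Bb, a protamine gene, by -4.97 and Arr1, an arrestin gene, by -4.87. In total 9266 genes were called, 6619 higher and 2647 lower (71.4% higher, but 37.4% with median-of-ratios scaling and 58.5% with quantile normalization), and 4665 rose and 1904 fell at least 2-fold.

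The comparison of mip40 with wt addressed the genes that change with the loss of this second tMAC subunit. CycB was higher, at 208.9 ± 9.51 FPKM in mip40 against 73.67 ± 7.72 in wt (SD, n = 2), a log2 fold change of 1.5 (SE 0.08, limma adjusted p = 1.75e-07). The size of this rise depends on the scaling too. Median-of-ratios scaling moved genes with a mean FPKM of at least 10 in both groups by a median of -1.09. twe changed by -0.87, bol by -0.88, fzo by -1.54, dj by -3.48 (SE 0.22) and betaTub85D by -2.21. Spermatid differentiation genes fell in 31 and rose in 1 of 32 (median -1.96, camera adjusted p = 4.09e-10, adjusted p = 0.362 with an estimated correlation). Cup genes fell in 15 of 17 and none rose (median -1.80, camera adjusted p = 2.07e-07, adjusted p = 0.27 with an estimated correlation), with w-cup at -4.74. tMAC and tTAF genes rose in 13 of 14 and none fell (median 1.56, but 0.49 with median-of-ratios scaling, camera adjusted p = 0.00478, adjusted p = 0.363 with an estimated correlation), with sa at 1.80. DNA replication genes rose in 25 of 28 and none fell (median 1.58, but 0.78 with median-of-ratios scaling, camera adjusted p = 7.82e-04, adjusted p = 0.27 with an estimated correlation), with PCNA at 2.45. Y-linked genes fell in 6 of 7 (median -2.12, camera adjusted p = 0.00328, adjusted p = 0.246 with an estimated correlation). Testis-specific proteasome genes rose in 4 and fell in 8 of 14 (median -1.01, camera adjusted p = 0.0351, adjusted p = 0.27 with an estimated correlation), with Prosbeta5R1 at -6.57. This call ended in 5 of the alternatives, where the camera adjusted p was 0.0504 to 0.085. Ribosomal protein genes rose in 89 and fell in 3 of 93 (median 1.29, but 0.18 with median-of-ratios scaling, camera adjusted p = 7.17e-10, adjusted p = 0.402 with an estimated correlation). General proteasome genes rose in 30 of 30 (median 1.06, but -0.04 with median-of-ratios scaling, camera adjusted p = 1.1e-05, adjusted p = 0.415 with an estimated correlation), a call that this scaling ended (camera adjusted p = 0.493). Counts adjusted over the list alone were the same.

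Gr63a, a carbon dioxide receptor gene, was at 82.7 ± 10.5 FPKM in mip40 and 0.31 ± 0.13 in wt (SD, n = 2), a rise of 6 (SE 0.19). Pxt, a peroxidase gene, rose by 5.63 and wb, a laminin gene, by 3.88, while scpr-A changed by -7.95, Acyp by -6.92 and Glut3, a sugar transporter gene, by -6.67. In total 9500 genes were called in mip40, 6202 higher and 3298 lower (65.3% higher, but 38% with median-of-ratios scaling), and 4526 rose and 2578 fell at least 2-fold. The median change of all genes tested was 0.21 in bam, 0.59 in comr, 0.62 in can and 0.46 in mip40 against wt, and -0.46, -0.22, -0.19 and -0.27 with median-of-ratios scaling. Among the genes with a mean FPKM of at least 10 in both groups, this scaling moved the values more, by a median of -1.10 in bam, -1.21 in comr, -1.16 in can and -1.09 in mip40, and the sign changed for 897, 1174, 1299 and 1141 called genes. geminin in mip40 was at 0.90, but -0.19 with this scaling. Median falls were larger with it, such as -1.64 for the Y-linked genes in can and -3.07 for the spermatid differentiation genes in mip40.

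The comparison of CG9879 with wt gave small differences in the stage markers. dj was at 1569 ± 104 FPKM in CG9879 and 1799 ± 86.7 in wt (SD, n = 2, adjusted p = 0.672, limma), and the differences of CycB, twe, bol, fzo and betaTub85D did not pass either. vas, at 8.99 ± 0.31 FPKM against 15.75 ± 0.98, was lower (limma adjusted p = 1.14e-04), can changed by -0.47 and mip40 by 0.89. Acyp was at 3.14 ± 1.88 FPKM against 153.4 ± 14.6 (log2 fold change -5.30, SE 0.34), Arr1 changed by -4.28 and the near-identical amylase genes Amy-d and Amy-p by -3.67 and -3.65. tun rose by 2.57, Cyp4p1, a cytochrome P450 gene, by 2.43 and Tsf1, a transferrin gene, by 1.59. Of 93 ribosomal protein genes 14 rose, or 20 adjusted over the list alone (median 0.16, camera adjusted p = 1.35e-08, adjusted p = 0.415 with an estimated correlation). Of 8 photoreceptor genes 3 fell, Arr1, Rh5 (-1.26) and ninaC (-0.71), and 1 more rose when adjusted over the list alone (median -0.37, camera adjusted p = 0.0422, adjusted p = 0.27 with an estimated correlation). Of 15 neuron genes 2 fell, nSyb (-1.30) and Rdl (-1.49), or 3 adjusted over the list alone (median -0.20, camera adjusted p = 0.0202, adjusted p = 0.31 with an estimated correlation). None of the 21 muscle genes was called, also adjusted over the list alone (median 0.49, camera adjusted p = 0.00422, adjusted p = 0.681 with an estimated correlation). Of the 32 spermatid differentiation genes 1 rose and 1 fell (median 0.04, camera adjusted p = 0.582). In total 1492 genes were called, 553 higher and 939 lower, 173 and 363 of them at least 2-fold. The count was 989 without wt replicate 1 and 411 in a fit of these 4 libraries alone, and the authors' deposited table marked 180 transcripts. Calls ended without 1 library for can (limma adjusted p = 0.107 to 0.159, without CG9879 replicate 2 or either wt library), Rh5 (limma adjusted p = 0.0603 to 0.0964, without any 1 of the 4), the photoreceptor list (camera adjusted p = 0.0969 without CG9879 replicate 1 and 0.136 without wt replicate 2) and the neuron list (camera adjusted p = 0.0901 without wt replicate 2). The photoreceptor call ended in 7 other alternatives too, where the camera adjusted p was up to 0.29 with quantile normalization and 0.332 with a filter at an FPKM of 5, the filter with which the neuron call also ended (camera adjusted p = 0.0509). In the fit of 4 libraries alone vas, nSyb and Tsf1 lost their calls (limma adjusted p = 0.0715, 0.0597 and 0.0713), and without the libraries with accessory gland transcripts the muscle list (camera adjusted p = 0.121), nSyb and Amy-d did (limma adjusted p = 0.0875 and 0.0881). The tables of CG9879 and wt were made on different gene annotations, so annotation and genotype coincide in this comparison.

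The comparison of mip40/bam with bam addressed which genes change with the loss of mip40 in testes without spermatocytes. Here too an effect on a gene and a change in the mix of cells or tissues cannot be told apart. dj was listed at 0 in both mip40/bam libraries and had 0.37 FPKM in bam, and betaTub85D and fzo did not pass. bol was at 5.10 ± 1.02 FPKM in mip40/bam and 26.94 ± 5.78 in bam (SD, n = 2), a log2 fold change of -2.19 (SE 0.15, limma adjusted p = 8.55e-06). Arp53D, an actin-related gene of the testis, was at 38.64 ± 1.40 FPKM against 0.10 in bam, a rise of 5.17 (SE 0.11), and Obp99a, an odorant-binding protein gene, rose by 4.49 and Gr63a by 4.24. mtrm, a Polo kinase inhibitor gene, changed by -2.99 and stai, the stathmin gene, by -2.28. Germline stem cell and spermatogonial genes fell in 6 of 12 and none rose (median -0.53, but -0.94 at equal summed FPKM, camera adjusted p = 0.00959, adjusted p = 0.362 with an estimated correlation), with AGO3, a piRNA pathway gene, at -1.79 and vas at -0.33. Of 11 meiotic cell cycle genes 3 fell, including tws at -0.67 (median -0.16, but -0.57 at equal summed FPKM, camera adjusted p = 0.0351, adjusted p = 0.443 with an estimated correlation). Testis-specific proteasome genes rose in 4 of 14, Prosbeta2R2 (4.03), Rpt6R (2.26), Rpn12R (1.61) and Rpt4R (0.95), and the median was 0.00 with a mean of 0.63 (camera adjusted p = 0.0208, adjusted p = 0.27 with an estimated correlation). General proteasome genes rose in 24 and fell in 1 of 30 (median 0.58, but 0.25 with quantile normalization and 0.16 at equal summed FPKM, camera adjusted p = 2.48e-10, adjusted p = 0.292 with an estimated correlation), with Prosbeta6 at 1.09. Ribosomal protein genes rose in 74 and fell in 1 of 93, or 79 and 1 adjusted over the list alone (median 0.48, but 0.06 with quantile normalization, camera adjusted p = 1.73e-18, adjusted p = 0.27 with an estimated correlation). Muscle genes rose in 13 and fell in 1 of 21, or 13 and 2 adjusted over the list alone (median 1.14, camera adjusted p = 0.00616, adjusted p = 0.702 with an estimated correlation), with Act57B at 2.22. Neuron genes rose in 1 and fell in 7 of 15 (median -0.35, camera adjusted p = 0.0414, adjusted p = 0.362 with an estimated correlation), with nSyb at 1.36 and Syx1A at -1.42. The neuron call ended in 7 alternatives, among them protein-coding genes that share no exon (median -0.02, camera adjusted p = 0.627), a filter at an FPKM of 5 (0.373), equal summed FPKM (0.236) and the fits without bam replicate 2 or mip40/bam replicate 2 (0.0523 and 0.0521). The meiotic call ended in 6, among them protein-coding genes that share no exon (camera adjusted p = 0.179), median-of-ratios scaling (0.0671) and the fit without mip40/bam replicate 1 (0.0523). The ribosomal call ended with quantile normalization (camera adjusted p = 0.248) and the testis-specific proteasome call without the 4 libraries with accessory gland transcripts (0.0831). The counts of the other lists named here were the same adjusted over the list alone. In total 4682 genes were called, 2127 higher and 2555 lower (45.4% higher, but 17.9% at equal summed FPKM), and 711 rose and 790 fell at least 2-fold. Annotation and genotype coincide here too.

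**Figure D4:**
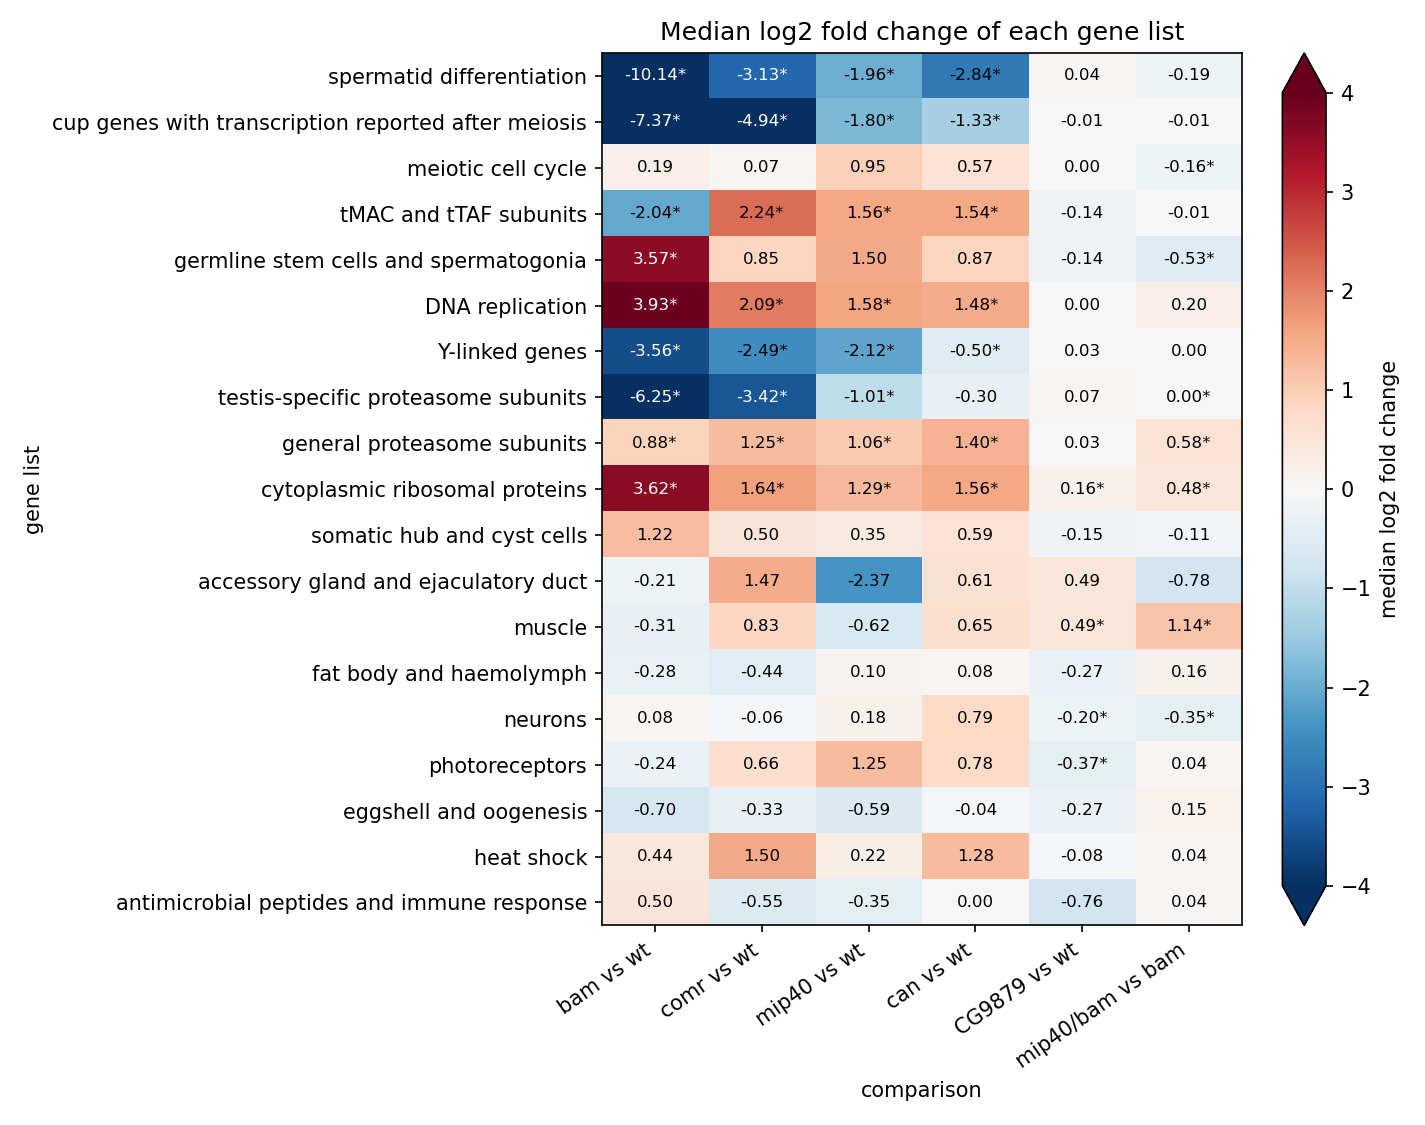
Cells give the median log2 fold change of each of the 19 gene lists (vertical axis) in 6 comparisons (horizontal axis), with the colour scale ending at 4 and -4; a star marks a camera adjusted p under 0.05. Spermatid differentiation, the top line, is at -10.14 in bam, -3.13 in comr, -1.96 in mip40, -2.84 in can and 0.04 in CG9879; no star remains with an estimated correlation.

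The remaining lists did not pass the camera test in these 6 comparisons, except the meiotic cell cycle list in mip40/bam against bam. Of 15 genes of somatic hub and cyst cells, the support cells of the testis, 10 rose and 2 fell in bam (median 1.22, camera adjusted p = 0.142). Of 14 heat shock genes 10 rose and none fell in comr (median 1.5, camera adjusted p = 0.091), and their summed FPKM was 4099 and 4189 in the comr libraries against 1540 and 1688 in wt. It was 4294 and 4393 in bam, 4333 and 4169 in can, 3116 and 2980 in mip40, 4799 and 4690 in mip40/bam and 1524 and 1426 in CG9879. Of 17 antimicrobial peptide and immune genes 5 rose and 1 fell in mip40/bam against bam (median 0.04, camera adjusted p = 0.358), where the list took 0.226% and 0.251% of the summed FPKM against 0.0663% and 0.0768%. Of 24 accessory gland and ejaculatory duct genes 2 rose in comr, or 1 adjusted over the list alone (median 1.47, camera adjusted p = 0.95). Their median and mean were positive while the camera direction was down. Of 9 fat body genes 2 rose and 4 fell in comr (median -0.44, camera adjusted p = 0.514), and of 10 eggshell and oogenesis genes 4 fell in bam (median -0.70, camera adjusted p = 0.285). Of the 11 meiotic cell cycle genes, 6 rose and 4 fell in bam, where the median of 0.19 and the mean of -0.21 differed in sign (camera adjusted p = 0.973). In comr 5 rose and 3 fell (median 0.07, mean -0.29, camera adjusted p = 0.775), in can 9 rose and 1 fell (median 0.57, camera adjusted p = 0.194) and in mip40 6 rose and 2 fell (median 0.95, camera adjusted p = 0.564). With median-of-ratios scaling the meiotic medians were -0.91 in bam, -0.56 in comr, -0.13 in can and 0.00 in mip40. The median of the somatic list in bam was then 0.25, those of heat shock, accessory gland and fat body genes in comr 0.37, 0.63 and -1.23, and that of eggshell genes in bam -1.22. The immune median in mip40/bam was -0.30 at equal summed FPKM. Except for the accessory gland list, these counts were the same adjusted over the list alone.

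The arrest mutants were compared directly. CycB was higher in mip40 than in comr by 5.66 (SE 0.08, limma adjusted p = 1.68e-10), sut4 by 7.27, SIP2 by 7.02 and Hsc70-2, a heat shock cognate gene, by 5.80. Hsp70Bb was lower in mip40 by -4.32, with replicates of 27.4 ± 19.2 FPKM in comr (SD, n = 2). In mip40 against comr, spermatid differentiation genes rose in 17 and fell in 3 of 32, or 18 and 3 adjusted over the list alone (median 0.95, camera adjusted p = 1.33e-04, adjusted p = 0.563 with an estimated correlation). Cup genes rose in 11 and fell in 1 of 17, or 12 and 2 adjusted over the list alone (median 1.57, camera adjusted p = 4.13e-04, adjusted p = 0.402 with an estimated correlation). tMAC and tTAF genes fell in 12 of 14, or 13 adjusted over the list alone (median -0.89, camera adjusted p = 6.5e-05, adjusted p = 0.27 with an estimated correlation). Heat shock genes rose in 1 and fell in 11 of 14, or 1 and 12 adjusted over the list alone (median -0.86, camera adjusted p = 0.0058, adjusted p = 0.48 with an estimated correlation). Muscle genes rose in 1 and fell in 15 of 21, or 1 and 17 adjusted over the list alone (median -1.24, camera adjusted p = 0.00213, adjusted p = 0.646 with an estimated correlation). Ribosomal protein genes rose in 2 and fell in 54 of 93, or 2 and 58 adjusted over the list alone (median -0.29, camera adjusted p = 1.83e-07, adjusted p = 0.443 with an estimated correlation), a call that ended with quantile normalization (camera adjusted p = 0.102). General proteasome genes rose in 1 and fell in 11 of 30 (median -0.19, but 0.04 at equal summed FPKM, camera adjusted p = 0.0115, adjusted p = 0.696 with an estimated correlation), a call that ended in 6 alternatives (camera adjusted p = 0.0529 without mip40 replicate 2, 0.129 without comr replicate 1 and up to 0.456 with quantile normalization). Meiotic cell cycle genes rose in 7 of 11 and none fell, or 7 and 2 adjusted over the list alone (median 0.40, camera adjusted p = 0.0225, adjusted p = 0.415 with an estimated correlation), which ended without comr replicate 2 (camera adjusted p = 0.079), without the 4 libraries with accessory gland transcripts (0.126) and with protein-coding genes that share no exon (0.0852). In total 5911 genes were called, 2933 higher and 2978 lower in mip40 (49.6% higher, but 60.1% with median-of-ratios scaling and 69.4% at equal summed FPKM). In comr against can, sut4 changed by -7.74, Hsc70-2 by -6.80, Prosbeta5R1 by -6.36 and Klp59C, a kinesin gene, by -6.27, and trpl rose by 3.22. Testis-specific proteasome genes rose in 3 and fell in 10 of 14, or 4 and 10 adjusted over the list alone (median -2.84, camera adjusted p = 0.0281, adjusted p = 0.27 with an estimated correlation), a call that ended without the 4 libraries with accessory gland transcripts (camera adjusted p = 0.0803) and with a pseudocount of 0.1 (0.0644). Cup genes rose in 3 and fell in 13 of 17, the same adjusted over the list alone (median -2.35, camera adjusted p = 0.00601, adjusted p = 0.483 with an estimated correlation). DNA replication genes rose in 14 and fell in 1 of 28 (median 0.49, camera adjusted p = 6.74e-04, adjusted p = 0.27 with an estimated correlation). tMAC and tTAF genes rose in 8 and fell in 3 of 14 (median 0.88, camera adjusted p = 0.0137, adjusted p = 0.415 with an estimated correlation), a call that ended with quantile normalization (camera adjusted p = 0.0876). Y-linked genes rose in 1 and fell in 6 of 7 (median -1.72, but -0.50 with quantile normalization, camera adjusted p = 0.0348, adjusted p = 0.27 with an estimated correlation), and this call ended in 6 alternatives, where the camera adjusted p was 0.056 to 0.171. Adjusted over the list alone the counts of the last 3 lists were the same. In total 7095 genes were called, 2943 higher and 4152 lower in comr (41.5% higher, but 62.4% with quantile normalization).

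In comr against bam, spermatid differentiation genes rose in 29 and fell in 1 of 32 (median 6.03, camera adjusted p = 1.81e-09, adjusted p = 0.365 with an estimated correlation), with Mst84Dc at 10.12, ocn at 10.11 and S-Lap1 at 9.91. DNA replication genes rose in 1 and fell in 18 of 28 (median -1.14, camera adjusted p = 3.21e-06, adjusted p = 0.246 with an estimated correlation). Germline stem cell and spermatogonial genes rose in 2 and fell in 9 of 12 (median -2.26, camera adjusted p = 0.00195, adjusted p = 0.273 with an estimated correlation), and Df31 changed by -4.84. tMAC and tTAF genes rose in 14 of 14 (median 4.47, camera adjusted p = 1.78e-07, adjusted p = 0.246 with an estimated correlation). Of 93 ribosomal protein genes, 2 rose and 87 fell, or 2 and 88 adjusted over the list alone (median -2.04, but -1.03 with quantile normalization, camera adjusted p = 6.95e-29, adjusted p = 0.246 with an estimated correlation). Cup genes rose in 11 of 17 and none fell (median 1.94, camera adjusted p = 0.00104, adjusted p = 0.415 with an estimated correlation), and testis-specific proteasome genes rose in 11 of 14 and none fell (median 1.14, camera adjusted p = 0.00328, adjusted p = 0.246 with an estimated correlation). Adjusted over the list alone the other counts were the same. In total 7746 genes were called by limma, 4497 higher and 3249 lower in comr (58.1% higher, but 42.3% with quantile normalization).

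The effect of mip40 was tested for a difference between the bam and the wt background as an interaction, the change in mip40/bam against bam minus that in mip40 against wt. scpr-A, with an interaction of 9.84 (SE 0.63, limma adjusted p = 8.56e-07), was at 3.08 ± 0.09 FPKM in mip40 and 1017 ± 210 in wt, and at 6.63 ± 1.63 in mip40/bam and 1.32 ± 1.59 in bam (SD, n = 2). Pxt had an interaction of -4.66 (SE 0.16) and wb of -4.76. In total 9084 genes were called, 3361 positive and 5723 negative (37% positive, but 64.4% with median-of-ratios scaling), and the median over all genes was -0.49, or 0.38 with median-of-ratios scaling.

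The 3009 genes at least 2-fold lower in comr than in wt were tested as a list in mip40/bam against bam, a comparison that shares no library with the one that chose them. Of these, 2288 (76%) had a mean FPKM under 1 in both bam and mip40/bam, against 32% of all genes tested, so most of them had no room to fall there. The median over the 3009 was 0.00 (camera adjusted p = 0.83). At equal summed FPKM, where the median of all genes was -0.17, the test passed in the upward direction with a median still at 0 (camera adjusted p = 0.000572). Of the other 721 genes 193 rose and 190 fell. Among genes with a mean FPKM of at least 1 in bam or mip40/bam, a restriction chosen after seeing the data, their median was -0.04 while the camera direction was up (camera adjusted p = 0.798). The 4849 genes at least 2-fold higher in comr had a median of 0.00 too (camera adjusted p = 0.83), but -0.34 with a camera adjusted p of 0.000662 at equal summed FPKM.

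Calls overlapped between the mutants. comr and mip40 shared 5480 genes higher and 3027 lower than wt, where independent lists of these sizes share 3010 and 920. comr and can shared 5458 and 2402 (independent, 3212 and 738), can and mip40 5410 and 2273 (independent, 3165 and 673) and bam and comr 4678 and 3261 (independent, 2782 and 1246). Called in opposite directions were 213, 462, 393 and 941 genes, in that order. At least 2-fold lower in all 3 of comr, can and mip40 were 1559 genes, and 3174 were at least 2-fold higher. These counts are without further scaling and were not taken with the other scalings. With median-of-ratios scaling 3446, 3040 and 3296 genes were called higher in comr, can and mip40, whatever the size of the change. That is fewer than the shared higher genes of these mutants above, so the shared higher counts depend on the scaling. All these comparisons used the same 2 wt libraries. Across genes, the log2 fold changes correlated at r = 0.85 for comr and mip40, 0.75 for comr and can, 0.75 for can and mip40 and 0.79 for bam and comr. In 20 simulated datasets of unchanged groups against shared controls r was 0.49 to 0.50, with 0 shared calls by limma. No gene was changed in them, so hardly any calls could arise, and the 0 is no baseline for the shared calls. Nor did they hold a shift of scale common to the comparisons with wt. The covariance was 4.26 for comr and mip40 (simulated 0.112), 3.06 for comr and can (simulated 0.111), 2.32 for can and mip40 (simulated 0.111) and 6.44 for bam and comr (simulated 0.115). For CG9879 with the other mutants r was 0.11 to 0.20, the covariance 0.18 to 0.26 (simulated 0.108 to 0.112), and 275 to 373 higher and 379 to 553 lower genes were shared (independent, 244 to 282 and 192 to 323), while 479 to 517 were called in opposite directions. With 2 wt libraries the controls could not be split, and part of the excess may come from the shared controls.

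The authors' deposited tables of the 6 comparisons list transcripts of an older annotation. They marked 6060 transcripts as significant in bam (3147 higher, 2913 lower), 5172 in comr (2731 and 2441), 5566 in can (2521 and 3045), 180 in CG9879 (99 and 81), 5942 in mip40 (2852 and 3090) and 3934 in mip40/bam against bam (1905 and 2029). Over 10736 genes the log2 fold changes of the authors' deposited tables and those here correlated at r = 0.96 in bam, 0.952 in comr, 0.905 in can, 0.713 in CG9879, 0.932 in mip40 and 0.806 in mip40/bam. The direction was the same for 88.4%, 87.2%, 86.8%, 96.1%, 89.2% and 99.1% of the genes called here, in that order. Of the genes called here and at least 2-fold changed, 71.3%, 58%, 50.7%, 67.6%, 54.7% and 79.6% were at least 2-fold changed in the same direction in the authors' deposited tables, and 58.6%, 54.9%, 61.3%, 23% (76 of 330 in CG9879), 64.8% and 78.5% had a transcript marked as significant there.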

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

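The tests of explanations in this part, and the list tests among genes measured without spermatocytes, were all chosen after the result was seen; the interaction test itself and its list tests were fixed beforehand. The change with mip40 differed between the bam and the wt background for 9084 genes (limma, adjusted over 12971 genes). The 2 backgrounds also differ in cell types, with and without spermatocytes. Of the lists, testis-specific proteasome genes had an interaction median of 2.48, Y-linked genes of 2.2, cup genes of 1.9, spermatid differentiation genes of 1.75 and muscle genes of 1.95. DNA replication genes had a median of -1.48, tMAC and tTAF genes of -1.67 and ribosomal protein genes of -0.73, the last 0.41 with median-of-ratios scaling. With that scaling the others were 3.57 (testis-specific proteasome), 3.26 (Y-linked), 2.99 (cup genes), 2.88 (spermatid differentiation), 2.92 (muscle), -0.52 (DNA replication) and -0.58 (tMAC and tTAF). The camera adjusted p-values ran from 9.45e-08 (spermatid differentiation) to 0.012 (muscle), and none of these calls held with an estimated correlation, where the adjusted p-values were 0.246 (Y-linked and testis-specific proteasome genes), 0.27 (DNA replication), 0.31 (cup genes), 0.362 (tMAC and tTAF), 0.415 (spermatid differentiation), 0.58 (ribosomal proteins) and 0.748 (muscle). The muscle call also ended with median-of-ratios scaling (camera adjusted p = 0.0626). Called in opposite directions in the 2 backgrounds were 2104 genes, or 1700 with median-of-ratios scaling, 1813 with quantile normalization and 3108 at equal summed FPKM.

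Several of these lists were near 0 in both bam and mip40/bam. A mean FPKM under 1 in both was found for 7 of 7 Y-linked genes, 14 of 17 cup genes, 24 of 32 spermatid differentiation genes, 9 of 14 testis-specific proteasome genes and 5 of 14 tMAC and tTAF genes. For such members the interaction largely restates the change in mip40 against wt and does not measure an effect of mip40 in the bam background. Among genes with a mean FPKM of at least 1 in bam or mip40/bam, no Y-linked gene was left, and the cup (3 genes, median 0.21), tMAC and tTAF (9 genes, -1.33) and DNA replication (28 genes, -1.48) lists no longer passed (camera adjusted p = 0.262, 0.239 and 0.104). Spermatid differentiation (8 genes, median 2.07), testis-specific proteasome (5 genes, 1.23), ribosomal protein (91 genes, -0.75) and muscle genes (18 genes, 1.97) passed (camera adjusted p = 0.00126, 0.0108, 0.0116 and 2.85e-06). Accessory gland, immune and eggshell genes, which did not pass among all genes tested, passed here (camera adjusted p = 0.0037, 0.00391 and 0.0352). The p-values of this restricted fit were adjusted over its 180 tests, and no estimated correlation was tried in it. Of the 19 accessory gland genes left, 3 were called, all positive. wt replicate 1 had 83.3 times the summed gland FPKM of wt replicate 2, so this list call cannot be told apart from an effect of that library.

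Several technical explanations of the interaction were weighed. Different annotations behind the tables of mip40/bam and bam are argued against as the whole cause, since 88.5% of 7806 called genes had the direction of the difference between the authors' deposited tables, which use another annotation for every library (86% of 5934 with a mean FPKM of at least 1 in bam or mip40/bam). These shares also rest on mip40 and wt, which were tabulated on the same annotation. They therefore do not show how far annotations moved mip40/bam against bam. The interaction was not confined to genes near 0 without spermatocytes. Genes with a mean FPKM of at least 10 in all 4 groups are above the floor by choice, and 82.6% of them were called (2888 of 3498). This share was not counted with the other scalings. Median-of-ratios scaling moved genes with a mean FPKM of at least 10 in both groups by a median of -1.09 in mip40 against wt. In mip40/bam against bam the median shift was 0.04, so the share may depend on the scaling. For the 29.7% of called genes under 1 FPKM in both bam and mip40/bam, an effect of mip40 and a lack of room to fall cannot be told apart, because the levels in bam are already at the floor. The scaling is argued against as the whole cause, since 59.1% of the called genes (5367) kept call and direction in each of 3 other scalings (median-of-ratios, quantile and equal summed FPKM), though the others did not. The 59.1% is of all called genes, with those near 0 among them. It was not counted for the genes of at least 10 FPKM alone. By design the backgrounds differ in cell types, with and without spermatocytes. An interaction from this cannot be told apart from a different effect of mip40 within the same cells, and it was not tested.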

How the results depend on the processing

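Leaving out the 4 libraries with accessory gland transcripts together, and restricting the genes to protein-coding ones that share no exon or to those with the same start and end in both annotations, or for the comr and interaction lists to those with a mean FPKM of at least 1 in bam or mip40/bam, were chosen after seeing the data. The other alternatives were planned. Followed were 282 genes, counted per comparison, 71 list tests that passed, 2 lists from comr and the counts of calls. Of the gene values under an alternative, 4823 kept direction and side of the threshold, 159 lost the call, 15 gained it and 51 changed sign, and of the list values 1216, 131, 1 and 7 did. Of the list losses, 71 came from the estimated correlation. Fits without 1 library, and fits of the groups compared only, kept the genes tested in the full fit, and a lone library was assumed to vary like the other groups. A 2-fold threshold was not run for the 2 comr lists, which already use it, and some genes and lists give no value where a filter removed them. With 2 libraries per group and 3120000 to 7690000 fragments, low genes are measured least precisely.

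The replicate numbers were not taken to pair the libraries. Over the 21 pairs of genotypes the same-numbered deviations correlated at -0.48 to 0.48, over 0.1 in 4 and under -0.1 in 5. The largest, of either sign, were among comr, can, CG9879 and wt, which each have 1 library with accessory gland transcripts. For these genotypes the values cannot show whether the numbers mark pairs. The other pairs lay at -0.14 to 0.16. With the replicate number as a block, 10202 genes were called in bam, 9898 in comr, 9240 in can, 1395 in CG9879, 9491 in mip40, 4621 in mip40/bam, 7028 in comr against can, 5840 in mip40 against comr, 7697 in comr against bam and 9020 for the interaction.

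Without 1 library, calls ranged from 9782 to 9911 in bam, 9499 to 9824 in comr, 8761 to 8911 in can, 989 to 1275 in CG9879 (989 without wt replicate 1), 9084 to 9163 in mip40, 3415 to 4151 in mip40/bam, 6302 to 6412 in comr against can, 4815 to 5175 in mip40 against comr, 7106 to 7380 in comr against bam and 8482 to 8794 for the interaction, from fewer samples. Without the 4 libraries with accessory gland transcripts they were 10127, 9413, 8648, 1513, 9313, 4804, 6270, 5350, 7528 and 9039, in that order. With fewer genes tested, protein-coding and sharing no exon, they were 6050, 5911, 5677, 752, 5742, 2908, 4362, 3842, 4783 and 5454. At the stricter 2-fold threshold 536 were called in CG9879, 1501 in mip40/bam, 3737 in comr against can, 2502 in mip40 against comr and 5087 in comr against bam. In a fit of the groups compared only, with fewer samples, 411 were called in CG9879. The authors' deposited tables marked 6060 transcripts in bam, 180 in CG9879, 5566 in can, 5172 in comr and 5942 in mip40, on another annotation and with another test. Shared calls at the 2-fold threshold were 2703 higher for bam and can, 39 higher and 251 lower for bam and CG9879, 2867 higher for bam and mip40, 3616 higher for comr and can, 45 higher and 249 lower for comr and CG9879, 75 higher and 173 lower for can and CG9879, 3455 higher for can and mip40, and 47 higher and 210 lower for CG9879 and mip40. Shared calls were not counted with the other scalings.

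Signs changed for the following log2 values, and the cause was not tested. With median-of-ratios scaling they were -0.54 (aly) and -0.78 (Prosalpha2) in bam, -0.68 (Rpn12R), -0.94 (Rpn6), -0.085 (Prosalpha2) and -0.53 (RpL41) in comr, -0.62 (twe), -0.64 (vas), -0.56 (tbrd-1), -0.48 (geminin) and -0.63 (RpL41) in can, and -0.36 (tbrd-1), -0.19 (geminin), -0.73 (Rpn12R), -0.38 (Rpt3R), -0.78 (Rpn6), -0.061 (Prosalpha2), -0.64 (RpL41) and -0.067 (RpL39) in mip40. The ribosomal interaction was 0.41. With quantile normalization they were 0.365 (CycB), 0.024 (Rpt3R) and 0.109 (Rpn6) in bam, -0.379 (vas) in can, -0.097 (Mst87F) and -0.027 (bol) in CG9879, and 0.454 (bam), 0.145 (can) and 0.089 (fzo) in mip40/bam. At equal summed FPKM they were -0.023 (Mst87F) in CG9879, 0.206 (mip40) in mip40 and -0.136 (RpS29) in mip40/bam, and with a pseudocount of 0.1 bam in mip40/bam was at 0.683. Without 1 library, values ranged across 0 in mip40/bam against bam for bam (-1.131 to 0.836, the last without bam replicate 1), twe (-0.15 to 0.045), can (-0.08 to 0.021) and fzo (-0.038 to 0.002), in CG9879 against wt for Mst35Ba (-0.331 to 0.02), twe (-0.026 to 0.1), bam (-0.382 to 0.132), Mst87F (-0.091 to 0.095), bol (-0.008 to 0.102) and CycB (-0.203 to 0.008), and in bam against wt for CycB (-0.201 to 0.011). Without the 4 libraries they were 0.011 (CycB) in bam and 0.192 (bam), 0.045 (fzo), 0.055 (CycB), -0.024 (bol), 0.154 (aly) and 0.036 (sa) in CG9879. For the genes lower in comr, the direction in mip40/bam against bam changed at a median of 0 with a pseudocount of 0.1, with median-of-ratios scaling and without bam replicate 2, and at -0.07 with the groups compared only. At equal summed FPKM the median stayed 0 and the test passed (camera adjusted p = 0.000572). For the genes higher in comr it was 0.01 with quantile normalization and -0.34 at equal summed FPKM.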

Other observations

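All tests in this part were chosen after the results were seen, and the sets in the first paragraph were formed then too, giving 90 tests over 9 sets and 10 comparisons. Genes annotated as non-coding RNAs, of which 1262 were tested, fell more often than they rose in bam, comr, mip40 and can, and many were not called. In bam 132 rose and 715 fell (median -1.69, camera adjusted p = 1.04e-08, adjusted p = 0.0342 with an estimated correlation). In comr 188 rose and 647 fell (median -1.14, camera adjusted p = 2.03e-10, adjusted p = 0.0342 with an estimated correlation), and in mip40 176 rose and 572 fell (median -0.82, camera adjusted p = 1.13e-10, adjusted p = 0.0342 with an estimated correlation). In can 243 rose, 412 fell and 607 were not called, with a median of 0.00 (camera adjusted p = 2.9e-08, adjusted p = 0.0342 with an estimated correlation), and in CG9879 75 rose and 156 fell (median -0.01, camera adjusted p = 0.466). Many such genes overlap others and the use of strand is not given in the sources used here, so single members are uncertain.

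Genes of chromosome 4, a small and largely heterochromatic chromosome, were lower in mip40/bam than in bam. Of 88 tested, 47 fell and 2 rose (median -0.55, camera adjusted p = 2.31e-07, adjusted p = 0.587 with an estimated correlation), and the authors' deposited table had a median of -0.68 over 73 of them. In bam against wt 57 rose and 12 fell (median 1.12, camera adjusted p = 0.0044, adjusted p = 0.992 with an estimated correlation). In CG9879 against wt 1 rose and 13 fell (median -0.15, camera adjusted p = 0.00663, adjusted p = 0.994 with an estimated correlation), and the authors' deposited table had a median of -0.08 over 73 of them. In both mip40/bam against bam and CG9879 against wt the annotation behind the per-library tables coincides with genotype.

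The 1492 genes called between CG9879 and wt may come from the genotype or from the tables. Different gene annotations are argued against as the whole cause, because 96.1% of 1161 called genes had the direction of the authors' deposited table, which was made on another annotation, though 23% of the 330 changed at least 2-fold had a transcript marked as significant there. A processing or library difference shared by the 4 libraries tabulated with FBgn identifiers stays open: of the 883 called genes with a mean FPKM of at least 1 in bam or mip40/bam, 62.7% had the same sign in mip40/bam against bam, and so did 64.8% of the 622 of the 1492 called there too, values between the bounds of 80% and 60% set for and against it. Chromosome 4 genes and the neuron list were lower and the ribosomal protein and muscle lists higher in both comparisons (camera). None of these calls held with an estimated correlation, and no muscle gene was called in CG9879 against wt. A difference in genetic background, or between these libraries, coincides with genotype and stays open too.

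Accessory gland transcripts in 1 library each of wt, comr, can and CG9879 may come from gland tissue carried along with the testes. The levels of the 24 members correlated between each pair of these 4 libraries at a Spearman rho of at least 0.683, and 21 to 23 of them were higher than in the partner library, by 69.9 to 180 times in sum. Tissue of the whole fly is argued against, since fat body, muscle and neuron lists were at most 1.4 times the partner library. Both libraries of a pair have the same genotype, so no biological explanation was tested.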
